A study of Homo sapiens with 4 samples.

How the data were processed

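Total RNA from HEK293 cells, an immortalized human embryonic kidney line, was hybridised to 4 single-colour arrays. The cells carried a transgene for LGP2, an RNA helicase of the RIG-I-like receptor family, or for LGP2-4KR, a form of LGP2 whose abbreviation the labels do not define. Each line was sampled unstimulated and 12 h after transfection of 100 ng/ml short poly I:C, a synthetic double-stranded RNA. This gave 4 groups of 1 array each, so no group had a replicate and none of the 5 comparisons has a test or a standard error. The only test of single genes was an additive limma fit over line and stimulation, chosen after seeing the data, in which the lines and the times stand in for replicates. The number of arrays limits the precision of every ratio.

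Per the labels' protocols, the RNA was amplified to amino allyl aRNA, coupled to Cy5 and fragmented by the array maker's protocol. Per the file headers, each deposited scanner table gives the median intensity of each spot, on a linear scale in scanner units and not normalized. The headers also hold readings at 3 gains with least-squares fits between them. The series table deposited by the authors holds an intensity per gene probe. Set against the scanner values, it equals the spot median minus about the mean of the blank spots, multiplied so that the median of the given values of an array is 25. The largest residual of that relation was 0.0530. How the authors chose which spots to leave empty is not given in the sources used here. The table gave 20708 values for unstimulated LGP2 cells, 20813 for unstimulated 4KR cells, 22308 for stimulated LGP2 cells and 21876 for stimulated 4KR cells.

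Each array held 27456 spots, of which 24460 were gene probes and 384 were blank spots. A second scanner column, headed as background, followed the spot signal with a correlation of the logarithms between 0.991 and 0.997 and was therefore not used as a local background. The array's mean blank spot took its place, which departs from the plan made before the data were examined. Background was corrected with limma 3.58.1 in R 4.3.3 by the normexp method with an offset of 50, followed by quantile normalization over the 4 arrays and log2. The offset shrinks the ratios of dim genes, so deposited intensities are given beside some of the log2 ratios. In data simulated for the response of LGP2 cells over 24460 probes, 2.99% of probes with a true 2-fold change, 72.7% of those with 4-fold and 83.6% of those with 8-fold passed a measured 2-fold ratio, and 1 of 24260 unchanged probes did. The median log2 ratio of the probes simulated at 4-fold was 1.46. The simulated noise was independent between probes, with no shift by position on the array and no added non-specific signal at 12 h. Its SD per array, 0.069 on the log2 scale, came from ratios already shrunk by the offset. The share of unchanged probes that passed is therefore not an estimate of false calls on the real arrays.

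A probe counted as detected when its signal passed the mean plus 2 SD of the blank spots of that array. Detected were 83.2% of gene probes in unstimulated LGP2 cells, 83.8% in unstimulated 4KR cells, 89.2% in stimulated LGP2 cells and 88.0% in stimulated 4KR cells. The median signal of detected probes above the blank level was 44.5, 43.0, 51.9 and 62.8 scanner units in the same order, against a SD of blank spots between 1.05 and 1.28. The platform annotation named 1 gene for 21707 probes and several for 0, and 2753 probes stay unnamed here. Of the named probes, 21675 had a gene identifier found in the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Probes of the same gene were averaged, and 1 probe that the scanner had rejected on a single array was left out. This left 18639 genes, of which 17085 were detected on at least 1 array and 15738 on all 4. The files used here name no genome build, so no coordinates are given.

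The 5 comparisons were the response to stimulation in each line, the difference of those responses (4KR minus LGP2), and 4KR against LGP2 cells at each time. Genes were counted past a 2-fold ratio if detected on the brighter array of the pair, or on all 4 arrays for the difference of the responses. A gene detected on only the brighter array was given a lower bound, its normalized level over the higher of the dimmer array's lowest detected probe and its own level there. Gene lists were placed by the percentile of their median log2 ratio among 10000 random lists of equal size, matched on mean level in 20 bins, as a description of these arrays. Before the data were examined, 24 lists were fixed, and 2 further lists were chosen after seeing the data. Also fixed beforehand was the rule for named genes: DHX58, the gene of LGP2, on every array; up to 10 genes per direction with the largest ratios past 2-fold among those detected on both arrays; up to 5 per direction by lower bound; the 10 largest differences of the responses in each direction; and the 4 members of each list with the largest ratios. Any detected member of the lists of interferon genes, antiviral genes, RIG-I-like receptor pathway genes and chemokine and NF-kB genes could be named as well. A named gene outside the rule is marked as chosen after its values were seen.

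The alternatives fixed beforehand were median scaling, 75th percentile scaling, no normalization between arrays, plain subtraction of the blank level with a floor of 3.60, the deposited table, a stricter detection filter, no detection filter, the brightest probe per gene and a 3-fold threshold. Chosen after seeing the data were an offset of 16, a correction for position on the array, leaving out blocks 20, 21 and 24 of the 24 blocks, the deposited table rescaled on probes given on all 4 arrays, and an additive limma fit over line and stimulation. The position correction took from each spot the median deviation of the spots within 11 columns by 5 rows of its block. The steps were tested on simulated data and run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.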

Results

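RNA levels were measured in 2 transgenic HEK293 lines, carrying LGP2 or LGP2-4KR, before and 12 h after transfection of short poly I:C. Each of the 4 combinations of line and time was represented by 1 array, so none of the differences reported here has a replicate check. No array came from mock-transfected cells or from cells left untreated for 12 h. An effect of poly I:C therefore cannot be told apart from one of the transfection or of 12 h in culture. Ratios are log2 values after quantile normalization with an offset of 50, and intensities are those of the deposited table, in which each array has a median of 25.

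DHX58, the gene that encodes LGP2, had a deposited intensity of 41.4 in unstimulated LGP2 cells and 22.8 in unstimulated 4KR cells. After stimulation the intensities were 51.0 and 42.6. The log2 ratio of 12 h over 0 h was 0.01 in LGP2 cells and 0.39 in 4KR cells, and that of 4KR over LGP2 cells was -0.49 unstimulated and -0.10 stimulated. Whether the single DHX58 probe lies within the transgene is not known here, so its level does not check the labels. The probe lies in block 24 of the array, where the 2 responses differed for many probes.

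The first comparison asked how LGP2 cells differed between 12 h of short poly I:C and no stimulation. Genes of the interferon response were far higher at 12 h. IFIT1, IFIT3 and IFIT2, interferon-induced RNA-binding proteins, had log2 ratios of 6.58, 6.07 and 5.74, and their deposited intensities at 12 h were 4267, 1961 and 2030 against 17.2, 1.60 and 9.07 unstimulated. ISG15, a ubiquitin-like modifier, was higher by a log2 ratio of 4.83, and RIGI, the cytoplasmic RNA sensor RIG-I, by 4.15. IFNB1, which encodes interferon beta, had a log2 ratio of 4.06, with intensities of 7.82 unstimulated and 613.4 at 12 h. In all, 74 genes were at least 2-fold higher and 2 at least 2-fold lower.

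The other genes with the largest ratios in LGP2 cells were CXCL8, a neutrophil-attracting chemokine, at 3.30, IFI44L at 3.29, TNFAIP3, an inhibitor of NF-kB signalling, at 3.10, and IFI6 at 2.78. The chemokine genes CXCL10, CCL5 and CXCL11 were not above background in unstimulated cells and were at least 31.8-fold, 13.9-fold and 4.83-fold higher at 12 h. OASL and IFI44, both interferon-induced, were likewise at least 22.9-fold and 5.89-fold higher. The 2 genes past 2-fold in the other direction were ITGB1, an integrin subunit, at -1.29 and CD63, a tetraspanin, at -1.03. Their probes lie in block 24, and with the position correction, chosen after seeing the data, the values were -1.20 and -0.92. The largest bounds on the lower side stayed below 2-fold, led by TAS2R13 at 1.58-fold. The same genes and their levels are in the plot of named genes on the 4 arrays.

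Grouped by the fixed lists, 23 of the 66 detected antiviral genes were at least 2-fold higher in LGP2 cells and 36 at least 1.5-fold, with 0 lower by 1.5-fold. Their median log2 ratio was 0.67, at percentile 100 of matched random lists. Beyond the IFIT genes, the list held IFIH1, the RNA sensor MDA5, at 2.44, IFITM1 at 2.36, ISG20 at 2.36, HERC5, the ligase for ISG15, at 2.21 and PLSCR1 at 2.05. Smaller ratios in the list were those of OAS1 at 0.78, EIF2AK2, which encodes the kinase PKR, at 0.73 and MX1 at 0.65. Of 30 detected chemokine and NF-kB genes, 7 were 2-fold higher, with a median of 0.31 at percentile 100, among them CXCL2 at 2.61 and NFKBIA, the inhibitor of NF-kB, at 2.12. Of 24 RIG-I-like receptor pathway genes, 3 were 2-fold higher, namely RIGI, IFIH1 and IRF7, an interferon regulatory factor, at 1.81, and the list's median was 0.15. MAVS, IRF3 and TBK1, the adaptor, transcription factor and kinase of the pathway, had ratios of -0.06, -0.08 and 0.29.

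Of 17 detected interferon genes, 2 were 2-fold higher in LGP2 cells. Besides IFNB1 this was IFNL3, a lambda interferon, which was not above background unstimulated and had an intensity of 43.5 at 12 h. IFNL1 was likewise not above background unstimulated and had an intensity of 30.9 at 12 h. The detected interferon alpha genes had ratios between -0.15 for IFNA8 and 0.13 for IFNA17. The interferon signalling list had 3 of 17 genes past 2-fold, IRF1 at 1.82, USP18 at 1.58 and IRF9 at 1.31. In the antigen presentation list, 2 of 17 passed, B2M at 1.20 and TAP1 at 1.13.

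Stress and growth lists were also among those that stood apart in LGP2 cells. The integrated stress and unfolded protein list had a median of 0.24 (percentile 99.99), or 0.15 to 0.52 over the settings tried, with 5 of 26 genes 2-fold higher, including ATF3, a stress-induced transcription factor, at 2.58, SLC3A2 at 1.70 and PPP1R15A at 1.56. Immediate early genes had a median of 0.14 with 5 of 24 genes 2-fold higher, among them EGR1 at 2.39 and JUN at 1.89. GADD45B, of the p53 target list, was at 2.45, and PMAIP1, of the apoptosis list, was at 1.55. Histone genes had a median of 0.38 (percentile 99.98) with 0 of 10 past 2-fold and H2AC6 at 0.98. Cholesterol synthesis genes had a median of -0.19 (percentile 0.49) with 0 of 19 past 2-fold, and MSMO1 at -0.43. Common control genes were as low, with a median of -0.23 (percentile 1.06). Without normalization between arrays the cholesterol median was above 0, but so was the median of all genes, at 0.13, and relative to it the list was lower in every scaling tried.

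The count of genes higher in LGP2 cells was 309 with plain subtraction of the blank level and 1332 in the deposited table, in which the median of all genes lay at 0.24. All 74 genes counted here were also past 2-fold in each of those settings. The genes lower numbered 85 with plain subtraction and 31 in the deposited table, against 2 here. Without normalization between arrays 175 genes were higher and 0 lower.

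The second comparison asked the same of 4KR cells, and the leading genes were the same. IFIT1, IFIT3 and IFIT2 were at 7.08, 6.07 and 5.79, ISG15 at 4.80, IFNB1 at 4.05 and RIGI at 4.01. CXCL8 was at 3.49, TNFAIP3 at 3.08, IFI44L at 2.92 and IFI6 at 2.63. CXCL10, OASL, CCL5, IFI44 and CXCL11, again not above background unstimulated, were at least 34.6-fold, 21.4-fold, 14.8-fold, 5.58-fold and 4.99-fold higher. In all, 68 genes were at least 2-fold higher and 1 lower. The gene lower, KRTAP2-2, a keratin-associated protein gene, was detected only on the unstimulated 4KR array and was at least 2.14-fold lower at 12 h.

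In 4KR cells 23 of 66 antiviral genes were 2-fold higher and 34 at least 1.5-fold, with a median of 0.67 (percentile 100). Chemokine and NF-kB genes had 7 of 30 past 2-fold and a median of 0.29 (percentile 100), with CXCL2 at 2.60 and NFKBIA at 2.59. The pathway list again had RIGI, IFIH1 at 2.38 and IRF7 at 2.02 past 2-fold and a median of 0.13. IFNL3 and IFNL1 were at 1.19 and 0.97, with intensities of 41.6 and 31.5 at 12 h. IRF1, USP18 and IRF9 were at 1.66, 1.76 and 1.27, while B2M and TAP1 were at 0.97 and 0.96, under 2-fold. The stress list had a median of 0.36, which fell to 0.10 without blocks 20, 21 and 24 and rose to 0.87 without normalization between arrays. It had 6 of 26 genes past 2-fold, among them ATF3 at 2.15, PPP1R15A at 1.42 and SLC3A2 at 1.21. EGR1 was at 2.47, JUN at 1.38, GADD45B at 2.56 and PMAIP1 at 1.69. Histone genes had a median of 0.37 and cholesterol synthesis genes of -0.34 (percentile 0.01), with HMGCS1 at -0.46. Common control genes had a median of -0.21 (percentile 2.12). The cholesterol median was above 0 without normalization between arrays, where the median of all genes lay at 0.28, and was lower than that median in every scaling tried. The count of genes higher was 248 with plain subtraction and 677 in the deposited table, each including all 68, and 50 and 33 were lower. Both counts of higher genes were below those of LGP2 cells. Without normalization between arrays that order was reversed, with 417 higher in 4KR cells against 175 in LGP2 cells. The median of all genes lay at 0.14 in the deposited table.

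The third comparison set the responses against each other, the question that the design of the 2 lines poses. Most of the leading interferon and chemokine genes had similar responses with the offset of 50, which shrinks dim genes. Of the genes 2-fold higher, 61 were shared between the lines, where independent lists of those sizes would share 0.295. Among these 61, the difference of the responses (4KR minus LGP2) had a median of -0.03 and ran from -0.51 for JUN to 0.50 for IFIT1, and 0 passed 1.5-fold. The IFIT1 probe lies in block 24, and with the position correction its difference was 0.29, against 0.78 with an offset of 16, 1.28 with plain subtraction and 1.16 in the deposited table. IFI44L was at -0.36, -0.80 with plain subtraction and -1.06 in the deposited table, where IFIT3 was at -0.80. Both differences rest in part on unstimulated intensities near background. In LGP2 and 4KR cells these were 2.82 and 4.30 for IFI44L and 1.60 and 2.60 for IFIT3. Of the 61, 1 passed 1.5-fold with an offset of 16, 2 with plain subtraction, 2 without normalization between arrays and 8 in the deposited table. The response was larger in LGP2 cells for 37 of the 61 and in 4KR cells for 24, but this split depended on scaling. It was 7 and 54 without normalization between arrays, with a median difference of 0.16. In the deposited table it was 51 and 10, with a median of -0.25, so the split gives no direction. Choosing genes past 2-fold in both lines favours small differences, so the 81 genes past 2-fold in either line were taken as well, 13 of them in LGP2 cells alone and 7 in 4KR cells alone. Their median difference was -0.03, and 6 passed 1.5-fold, named here after their values were seen. MSH6, SRSF4, EPC1 and KHDC4 were at -0.95, -0.76, -0.64 and -0.60, and HEXIM1 and ALKBH1 at 0.60 and 0.82. MSH6, SRSF4 and KHDC4 have their probes in block 21 and ALKBH1 in block 24. With the position correction 3 of the 81 passed 1.5-fold, namely MSH6 at -0.62, EPC1 at -0.67 and HEXIM1 at 0.68. SRSF4, KHDC4 and ALKBH1 came to -0.37, -0.46 and 0.47. The median difference of the antiviral list was -0.02, at percentile 9.38 of matched random lists, and was above 0 without normalization between arrays, where the median of all genes lay at 0.14. The lists outside the 95% range of random lists were cell cycle genes at -0.07 (percentile 0.86), stress genes at -0.06 (percentile 2.35) and keratinocyte markers at 0.07 (percentile 98.7), and with the position correction their medians were -0.03, -0.08 and 0.09. The cell cycle and stress medians were above 0 without normalization between arrays, but below the median of all genes. Across the 15738 genes detected on all arrays, the responses had a Pearson correlation of 0.83 and a Spearman correlation of 0.70 with no array in common, but genes are not independent replicates.

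**Figure D1:**
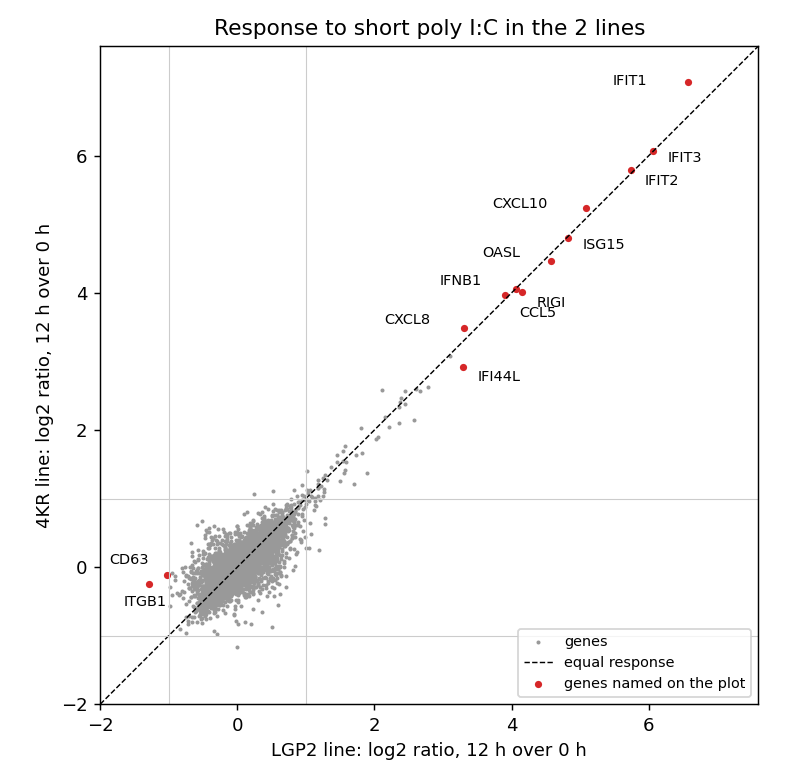
Log2 ratio of 12 h over 0 h in LGP2 cells (horizontal axis) and 4KR cells (vertical axis), with 1 point per gene detected on at least 1 array, a dashed line of equal response and thin lines at 2-fold. The named interferon and chemokine genes lie along the line of equal response from IFI44L to IFIT1, and ITGB1 and CD63 lie left of it.

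Genes whose responses differed by at least 2-fold numbered 4 with the higher value in 4KR cells and 6 with the lower. The 4 were FTSJ3, an RNA methyltransferase of ribosome synthesis, at 1.20, ESPNP, an espin pseudogene, at 1.20, ITGB1 at 1.04 and CSRNP3 at 1.03. The 6 were ZCCHC12 at -1.39, RAC3, a small GTPase, at -1.14, PDIA3, a disulfide isomerase of the endoplasmic reticulum, at -1.03, PFDN4, a prefoldin subunit, at -1.01, CTSZ, a cathepsin, at -1.01 and FMR1 at -1.01. In the deposited table these 6 ran from -1.16 for PFDN4 to -2.26 for CTSZ, a dim gene. Next in order were CRACR2B at 0.999, EME1 at 0.98, YTHDF3 at 0.95, SCNM1 at 0.94, CSTF2 at 0.93 and MRPL42 at 0.93 on the higher side, and HMGN1 at -0.96, MSH6 at -0.95, ACTN1 at -0.91 and CDC42 at -0.85 on the lower. FTSJ3, ITGB1, EME1, SCNM1, CSTF2 and MRPL42 have their probes in block 24, and RAC3, PFDN4, FMR1, CDC42, YTHDF3, HMGN1, MSH6 and ACTN1 in blocks 20 and 21. With the position correction, chosen after seeing the data, the counts were 2 and 2, and the values of FTSJ3 and FMR1, for example, were 0.84 and -0.67. RAC3, in block 20, stayed past 2-fold at -1.01, so the corrected counts still include a gene of the shifted blocks. Without normalization between arrays the counts were 20 and 1, with plain subtraction of the blank level 88 and 60, and 63 and 172 in the deposited table.

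**Figure D2:**
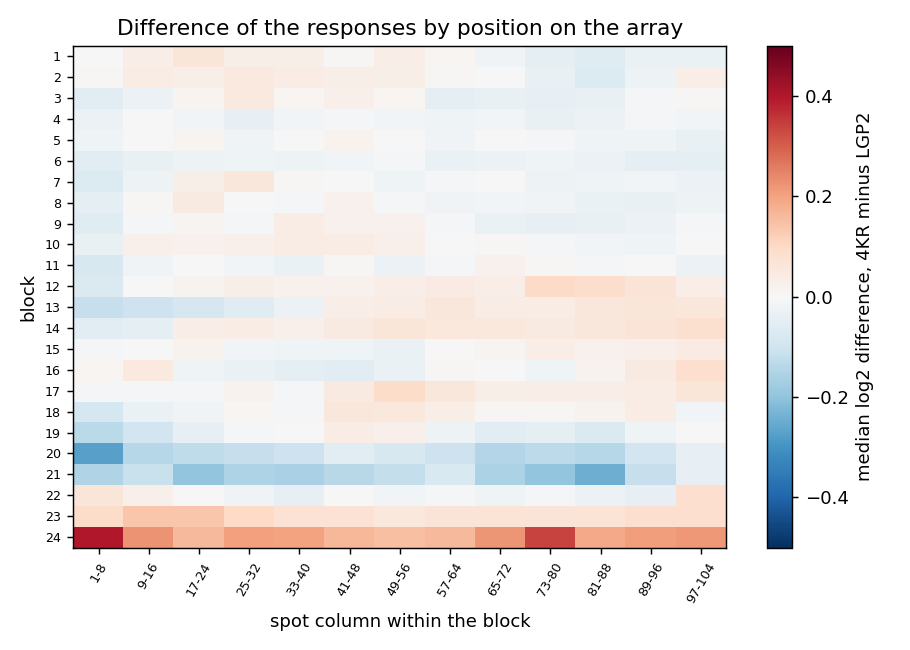
Median difference of the responses (log2, 4KR minus LGP2) over gene probes detected on all 4 arrays, by block of the array (vertical axis) and by groups of spot columns within the block (horizontal axis). Block 24 is above 0 and blocks 20 and 21 are below 0 along most of their columns.

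The fourth comparison, 4KR against LGP2 cells without stimulation, found few genes past 2-fold, 2 higher and 2 lower. ZCCHC12 was higher in 4KR cells by a log2 ratio of 1.01, with intensities of 241.6 and 106.6. KRTAP2-2, not above background in LGP2 cells, was at least 2.07-fold higher. CCN2, a secreted matricellular protein, was at -1.30, and KCTD12 was just past 2-fold lower with intensities of 75.7 in 4KR and 182.7 in LGP2 cells. The CCN2 value is the mean of 2 probes that disagreed, with a log2 ratio of -2.58 for a probe in block 24 (intensities 9.60 against 189.3) and -0.02 for a probe in block 3. CCN1, a related gene, was at -0.40. KCTD12 has its probe in block 24 and was at -0.84 with the position correction, which left only CCN2 past 2-fold lower. Plain subtraction of the blank level counted 24 genes higher and 48 lower, and 70 and 67 were counted in the deposited table.

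Lists of the interferon response did not stand apart between the unstimulated lines. The antiviral list had a median of 0.01 (percentile 69.9) with 0 of 66 genes past 1.5-fold, IFIT1 at -0.36 and ADAR, an RNA-editing enzyme, at 0.35. Chemokine and NF-kB genes had a median of 0.02 and RIG-I-like receptor pathway genes of 0.01. Histone genes had a median of 0.11 (percentile 99.95), led by H1-2 at 0.48, and p53 targets had a median of 0.08 (percentile 99.81), led by MDM2 at 0.50. In both lists 0 genes passed 1.5-fold.

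The fifth comparison, 4KR against LGP2 cells at 12 h, counted 2 genes higher and 0 lower. These were ESPNP, with intensities of 114.6 in 4KR and 39.0 in LGP2 cells, and CRACR2B at 1.01, with intensities of 238.9 and 116.3. With the position correction CRACR2B was at 0.99. CCN2 was at -0.87, again the mean of the same 2 probes, and CCN1 at -0.34. Among antiviral genes the largest ratios were RSAD2 at 0.33 and IFI44L at -0.30, and the list's median was -0.0033 (percentile 42.0). The chemokine median was 0.01, with CXCL8 at 0.27, and the pathway median -0.03, with NFKB1 at -0.25 and IRF7 at 0.22. Cholesterol synthesis genes had a median of -0.10 (percentile 0.08), with SQLE at -0.41 and ACAT2 at -0.40, and a median above 0 without normalization between arrays, where the median of all genes lay at 0.12. The antiviral, chemokine and pathway medians took the opposite sign under at least 1 other setting, also relative to the median of all genes, and give no direction. Across genes the line differences at the 2 times had a Pearson correlation of 0.03, and of 0.08 with the position correction. Of the genes 1.5-fold lower in 4KR cells, 55 unstimulated and 7 stimulated, 1 was shared where independent lists would share 0.0225. It was CCN2, and its low value rests on the probe in block 24, at -1.70 stimulated. The probe in block 3, at -0.04, was again dim (intensities 8.70 in 4KR and 10.1 in LGP2 cells). An overlap of 1 gene is no sign of a line difference that repeats across genes. Plain subtraction counted 40 genes higher and 22 lower at 12 h and 46 and 204 were counted in the deposited table, with the median of all genes at -0.11.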

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

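All tests in this part other than the count of arrays per line and time were chosen only after the result was seen. In 9 genes the 12 h array lay above the 0 h array in 1 line and below it in the other, and the responses differed by at least 2-fold. With 1 array per group this difference was not tested. The log2 difference, 4KR minus LGP2, was 1.20 for FTSJ3, 1.20 for ESPNP, 1.03 for CSRNP3, -1.39 for ZCCHC12, -1.14 for RAC3, -1.03 for PDIA3, -1.01 for PFDN4, -1.01 for CTSZ and -1.01 for FMR1. ZCCHC12, for instance, had intensities of 106.6 and 191.5 in LGP2 cells and 241.6 and 130.9 in 4KR cells.

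Position on the array may account for many of the differences between the responses. Of 205 probes whose responses differed by over 1.5-fold, 78.5% lay in the 3 fullest of the 24 blocks, against an upper end of 22.4% of the 95% range over 10000 random placements. A local correction left 94 such probes. Of these, 51 still lay in the 3 blocks, which held 12.5% of probes, so it did not remove the clustering. Of the 5 genes past 2-fold outside blocks 20, 21 and 24, 3 stayed past 2-fold with the correction (ZCCHC12 at -1.38, ESPNP at 1.18 and CSRNP3 at 1.04). PDIA3 and CTSZ, at -1.03 and -1.01 before, each came to -0.98, a shift below the 0.12 spread of bright positive control spots. The correction left at least 94.6% of the difference in each of the 5 and 66.3% to 88.2% in the genes inside the blocks, but it takes medians over 5 spot lines and can miss a trend at the edge of a block. Of the 10 largest lower differences, 9 lay in the first spot line of their block, 7 of them in blocks 20 and 21. Outside the 3 blocks 4 of 21 probes lower by 1.5-fold lay in that line, which over all blocks held 10.3% of detected probes. Neighbours in the same line, within 10 columns and at most 2-fold dimmer, were compared with each gene. Their median difference was 6.94% of the gene's own around CTSZ (17 neighbours), 8.58% around ESPNP (5) and 5.34% around ZCCHC12 (3). These 3 genes were grouped after those values were seen, so the group is no test of a trend across neighbouring spots. The values show only that the spots compared shared little of each difference, over few spots for ESPNP and ZCCHC12. A trend across neighbouring spots stays open for PDIA3, with a median of 29.8% over 3 neighbours, and for CSRNP3, with only 2 neighbours. A blemish at a single spot stays open for all 5. A different response of the 4KR line stays open, since there was 1 array per line and time.

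Outside the genes with names, 3 unnamed probes were at least 2-fold higher at 12 h in both lines, a signal in data that no comparison above used. Their intensities in LGP2 cells were 59.5, 56.1 and 19.97 unstimulated and 400.3, 283.2 and 99.3 at 12 h, and in 4KR cells 62.9, 59.1 and 25.1 unstimulated and 304.3, 212.2 and 108.3 at 12 h. There were 2753 unnamed probes, so this is 0.109% of them, against 0.327% of named genes.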

How the results depend on the processing

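An offset of 16, the position correction, leaving out blocks, the rescaled deposited table and the additive fit were chosen after seeing the data. The counts rest on 1 array per group and on how background and scaling treat dim genes, since detected probes had a median signal of only 43.0 to 62.8 units above blank. No paired analysis was possible for any of the 5 comparisons, because each rests on single arrays, so that arrays of the same line could be blocked only over both lines together, in the additive fit. For the same reason no array could be left out. Of 190 values recomputed for the counts and antiviral medians, 96 stayed within their limits, 94 moved and 0 called values reversed. A count has no sign, so the counts could not reverse. Some antiviral medians near 0 did change sign. Without normalization between arrays that of the difference of the responses went from -0.0193 to 0.13. That between the stimulated lines went from -0.0033 to 0.12. The cause was not tested for the values that follow. For 51 named ratios, 251 of 485 recomputed values stayed within 0.12, the spread of bright positive control spots. Of the other 234, 188 were larger, and 1 changed sign, that of DHX58 between the stimulated lines, at 0.04 without normalization between arrays. That spread is the largest SD of the log2 ratio of a positive control between arrays and does not measure the noise of dimmer genes. In an additive limma fit, which assumes equal responses and has 1 residual degree of freedom per gene, 1375 genes were higher and 1268 lower with stimulation at an adjusted p of 0.05, and 0 differed by line in either direction, with 832 at an unadjusted p under 0.05. After the position correction the fit gave 2091 and 1835 with stimulation and again 0 by line, with 1018 unadjusted. Most of these shifts were small, since with and without the correction only 68 of the higher genes and 0 of the lower were past 2-fold.

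The values that moved are given here as numbers of genes higher or lower and as medians of the antiviral list. Median scaling gave for the LGP2 response 5 lower and for the 4KR response 2 lower. For 4KR against LGP2 unstimulated it gave 4 lower and for 4KR against LGP2 stimulated 1 higher. 75th percentile scaling gave for the LGP2 response 6 lower and for the 4KR response 2 lower. For 4KR against LGP2 stimulated it gave 1 higher. No normalization between arrays gave for the LGP2 response 175 higher, 0 lower and for the 4KR response 417 higher, 0 lower, antiviral median 0.99. For the difference of the responses it gave 20 higher, 1 lower, antiviral median 0.13 and for 4KR against LGP2 unstimulated 0 higher, 6 lower. Further, it gave for 4KR against LGP2 stimulated 4 higher, antiviral median 0.12. Plain subtraction of the blank level gave for the LGP2 response 309 higher, 85 lower, antiviral median 1.60 and for the 4KR response 248 higher, 50 lower, antiviral median 1.31. For the difference of the responses it gave 88 higher, 60 lower, antiviral median -0.074 and for 4KR against LGP2 unstimulated 24 higher, 48 lower. For the stimulated lines it gave 40 higher, 22 lower. The deposited table gave for the LGP2 response 1332 higher, 31 lower, antiviral median 1.99 and for the 4KR response 677 higher, 33 lower, antiviral median 1.66. For the difference of the responses it gave 63 higher, 172 lower, antiviral median -0.20 and for 4KR against LGP2 unstimulated 70 higher, 67 lower, antiviral median 0.068. Further, it gave for 4KR against LGP2 stimulated 46 higher, 204 lower, antiviral median -0.10. The stricter detection filter gave for the 4KR response 0 lower and for 4KR against LGP2 unstimulated 1 higher. The brightest probe per gene gave for 4KR against LGP2 unstimulated 4 lower and for 4KR against LGP2 stimulated 1 lower. The 3-fold threshold gave for the LGP2 response 32 higher, 0 lower and for the 4KR response 33 higher, 0 lower. For the difference of the responses it gave 0 higher, 0 lower and for 4KR against LGP2 unstimulated 0 higher, 0 lower. For the stimulated lines it gave 0 higher. An offset of 16 gave for the LGP2 response 119 higher, 12 lower, antiviral median 1.01 and for the 4KR response 9 lower, antiviral median 0.96. For the difference of the responses it gave 14 higher, 11 lower and for 4KR against LGP2 unstimulated 7 higher, 8 lower. Further, it gave for 4KR against LGP2 stimulated 3 lower. The local position correction gave for the LGP2 response 1 lower and for the difference of the responses 2 higher, 2 lower. For 4KR against LGP2 unstimulated it gave 1 lower and for 4KR against LGP2 stimulated 1 higher. Leaving out blocks 20, 21 and 24 gave for the LGP2 response 0 lower and for the difference of the responses 2 higher, 3 lower. For 4KR against LGP2 unstimulated it gave 0 lower. The deposited table rescaled on shared probes gave for the LGP2 response 707 higher, 77 lower, antiviral median 1.74 and for the 4KR response 402 higher, 56 lower, antiviral median 1.49. For the difference of the responses it gave 81 higher, 123 lower, antiviral median -0.12 and for 4KR against LGP2 unstimulated 69 higher, 71 lower, antiviral median 0.052. For the stimulated lines it gave 54 higher, 158 lower, antiviral median -0.034.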

Other observations

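The tests of position, of YAP targets, of control spots and of basement membrane genes in this part were chosen after the result was seen. Several genes were lower at 12 h in both lines by less than the 2-fold level. At 1.5-fold, 85 genes were lower in LGP2 cells and 71 in 4KR cells, and 14 were shared where independent lists would share 0.353. The 14 were named after their values were seen, and the lowest were SPARC at -0.84 and -0.90, LAMB1, a laminin chain, at -0.75 and -0.96, COL4A1, a basement membrane collagen, at -0.75 and -0.73, and GPC3 at -0.72 and -0.83 in LGP2 and 4KR cells. LAMA5 was at -0.66 and -0.79, COL4A2 at -0.65 and -0.73, and PDIA4 at -0.72 and -0.79. All 14 were below 0 in both lines under each scaling tried. A list of basement membrane genes was written after these were seen. Without the 5 genes that prompted it, its other 16 detected genes had a median log2 ratio of -0.14 in LGP2 cells and -0.11 in 4KR cells, at percentiles 0 and 0.02 of matched random lists, and 15 of the 16 were below 0 in each line. Without normalization between arrays the medians were -0.0016 and 0.09, but -0.13 and -0.20 relative to the median of all genes. A lower level of basement membrane genes as a group at 12 h is a hypothesis that these values are in line with; the value of 1 of the 16, LAMA4, had been seen beforehand.

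OR9I1, an olfactory receptor gene chosen after its values were seen, was at 2.15 in LGP2 cells and 2.19 in 4KR cells, from intensities of 2.59 and 2.40 to 121.1 and 113.5. The values rest on a single probe, and whether it also matches another transcript could not be checked. In LGP2 and 4KR cells, heat shock genes had medians of 0.15 and 0.19 (0.0095 to 0.36 and 0.17 to 0.55 over the settings tried), cell cycle genes 0.10 and 0.0057, glycolysis and hypoxia genes -0.09 and -0.14, ribosomal protein genes -0.04 and -0.06, small RNA machinery genes -0.0064 and -0.02, and ubiquitin lysine-63 enzymes 0.12 and 0.04, with 4 of 22 past 2-fold in each line. The cell cycle medians were below 0 with median scaling, 75th percentile scaling and the rescaled deposited table, and in 4KR cells also with the brightest probe per gene. Common control genes had medians of -0.23 and -0.21 and included ACTB at -0.55 in 4KR cells. Without normalization between arrays the medians of glycolysis genes in both lines, and of ribosomal protein and control genes in 4KR cells, were above 0, with the median of all genes at 0.13 in LGP2 and 0.28 in 4KR cells; relative to it they were lower in every scaling tried. The small RNA machinery medians and the antigen presentation median of LGP2 cells changed sign under several scalings and give no direction. Apoptosis genes were at 0.05 and 0.05, p53 targets at 0.04 and 0.06, immediate early genes at 0.16 in 4KR cells, interferon genes at 0.04 and 0.03, interferon signalling genes at 0.15 and 0.07, and antigen presentation genes at -0.0015 and 0.07. The interferon gene medians ran from 0.0066 to 1.19 in LGP2 cells and from 0.02 to 0.50 in 4KR cells over the settings tried. Without normalization between arrays they lay below the median of all genes.

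Marker lists of cells that HEK293 cultures should not hold had small log2 ratios of 12 h over 0 h, which do not tell whether such cells were present. Detected on at least 1 array were 10 of 14 leukocyte, 9 of 13 fibroblast, 8 of 13 hepatocyte and 8 of 8 keratinocyte markers. In LGP2 and 4KR cells the leukocyte medians were -0.03 and -0.04, fibroblast -0.03 and -0.0033, hepatocyte 0.0051 and -0.0061, and keratinocyte 0.02 and 0.08. Neuronal-type genes that HEK293 cells express were at -0.05 and -0.08. Relative to the median of all genes, the leukocyte median of 4KR cells, the keratinocyte median of 4KR cells and both neuronal medians kept their sign in every setting tried, and the others did not. Between the stimulated lines the keratinocyte list had a median of 0.12 at percentile 100 over 8 genes, led by IVL at 0.18 and KRT14 at 0.17, and the leukocyte list 0.04 at percentile 98.7 over 10.

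CCN2, RBMS3, ANKRD1 and CCN1 were lower in 4KR cells at both times, at -1.30, -0.61, -0.26 and -0.40 unstimulated and -0.87, -0.46, -0.31 and -0.34 stimulated. RBMS3 and ANKRD1 were picked after their values were seen. Both were dim, so the offset shrinks their ratios. Unstimulated intensities in 4KR against LGP2 cells were 5.30 against 21.4 for RBMS3 and 3.40 against 9.15 for ANKRD1. At 12 h they were 5.70 against 19.4 and 3.70 against 11.8. Position on the array as the whole cause is argued against for RBMS3, ANKRD1 and CCN1, outside blocks 20, 21 and 24, since the local correction left at least 95.9% of each value and the median over 15 or more neighbours in the same spot line came to at most 15.1% of it. For CCN2 position stays open, because the low value rests on a probe in block 24, at -2.58 unstimulated against -0.0227 for a dim probe in block 3. CCN2, ANKRD1 and CCN1 are textbook targets of YAP, so a lower YAP target programme could account for them, but the other 16 listed targets had a median of 0.0092 unstimulated (percentile 64.6) and -0.03 stimulated (percentile 5.80), which leaves it open. A difference between cultures or clones unrelated to the transgene cannot be told apart from the transgene, because there was 1 line per transgene.

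The deposited table counted 1332 genes 2-fold higher in LGP2 cells, against 74 after quantile normalization. Scaling over different numbers of given values may be part of this, since scaling on the 20465 probes given on all 4 arrays lowered the count to 707, but that decided neither way. More non-specific signal on the 12 h arrays is a candidate explanation, as the 96 negative control spots lay 1.89 scanner units (SE 0.101) higher against the blank spots at 12 h in LGP2 cells and 1.43 (SE 0.148) higher in 4KR cells. The dimmest 4892 probes had median differences of 2.30 and 1.43 units. No biological explanation was tested for this pattern.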
